A study of Mus musculus with 8 samples.

How the data were processed

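The series holds 8 microarrays of the extensor digitorum longus (EDL), a fast hindlimb muscle, from 4 Swiss Webster mice. In each mouse the EDL of 1 leg contracted for 4 h under stimulation of its nerve, and the unstimulated EDL of the other leg served as the control. Per the labels' protocols, total RNA was copied into biotin-labelled cRNA and hybridised to 1-colour CodeLink arrays, with 6 bacterial control mRNAs added for scaling. Muscles other than the EDL were not analysed here.

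The deposited table gives 1 intensity per probe and array, on a linear scale, as normalized by the authors. Background correction and the exact scaling behind these intensities were not given in the sources used here. The 8 array medians lay between 0.90 and 0.94 intensity units, with a highest-to-lowest ratio of 1.04, so the values were used as deposited with no further scaling. The table holds 10500 probes, of which 6373 have 1 gene symbol, 0 have several and 4127 have none in the probe annotation used here. All 6373 symbols were brought up to date through their Entrez identifiers with the gene table of mouse assembly GRCm38.p6, which was used for names alone. Control probes carry no marking in the table, so any that it holds stayed among the unnamed probes and in the test.

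Intensities below 0.0937, the 5th percentile of all positive values, were raised to that floor before taking log2. The number of values below the floor ranged from 80 on the contralateral array of mouse 440 to 1387 on the stimulated array of mouse 183. A probe was tested where at least 3 mice had a value in both muscles, which left 10406 probes covering 6315 genes. The 4 pairs of arrays limit the precision, and the median standard error (SE) of a log2 change was 0.26.

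The mouse number in the sample titles pairs the muscles, since both come from the same animal. Deviations from the group means correlated within every pair, at 0.59 in mouse 183, 0.64 in mouse 197, 0.58 in mouse 438 and 0.52 in mouse 440. They were not set against correlations between mice. A difference between mice 183 and 197 and mice 438 and 440 would also raise them, so the pairing rests on the titles. The test was limma (version 3.58.1, in R 4.3.3) with mouse as a block and an intensity trend in the variance prior, followed by Benjamini-Hochberg adjustment over all tested probes and a two-sided threshold of adjusted p 0.05. A change is the log2 intensity of the stimulated muscle minus that of the contralateral muscle, fitted over the mice, and folds are on this floored scale. The median change of all tested probes was -0.14 on this scale, and cyclic loess, an alternative chosen after seeing the data, moved it to -0.01. Changes are given on the deposited scale unless a sentence says otherwise. The SE of a change, also after ±, is limma's moderated SE unless a sentence names an SD or an SE over mice or genes. Moderation draws each probe's variance toward a value shared by probes of like intensity. For a gene that varied widely between mice, such as Jun, this SE is smaller than its own values alone would give.

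A set of 22 gene lists was fixed before the data were examined, covering fibre type, activity response, stress, metabolism and markers of the other cell types a muscle can hold. Lists with at least 5 measured genes, 19 in all, were tested with limma's camera at a preset correlation of 0.01, with 1 probe per gene, the brightest, over 6245 genes with complete values, and adjusted over the lists. Each list was also tested with an estimated correlation and with fry, whose directional test asks whether a set's genes move on balance 1 way and whose mixed test asks whether they change in either direction. For each list the median change was also set against 10000 random lists drawn from the 100 genes nearest in brightness to each member, which describes these arrays and was chosen after seeing the data. Counts over the list alone use the same p-values adjusted within the list. Camera sets a list against the other genes, and the median change of all tested probes was -0.14. Its direction can therefore differ from the sign of a list's own mean or median.

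The genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among genes past the threshold with the same direction in every mouse, up to 4 members of each list by smallest p, and every measured gene that the study itself named. Other genes are said to be chosen after their values were seen. The rule gave 107 genes.

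The fit was tested on simulated data made from 10245 probes, with 200 changed probes in each of 10 draws. It recovered 51.8% of 2-fold changes and 99.4% of 4-fold changes, with 0% in the wrong direction, and 7.07% of its calls were false. Camera found 20 of 20 simulated lists shifted by 0.5 on the log2 scale and called 1 of 100 unshifted lists, at unadjusted p under 0.05. Simulated probes varied independently of each other, whereas the estimated correlation in the real lists reached 0.55, in the heat shock list. These rates therefore do not show how camera at the preset correlation behaves for correlated genes.

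Alternatives fixed beforehand were no block for the mouse, the mouse as a random effect (with statmod 1.5.0), quantile normalization, median scaling, no floor, a floor at the 20th percentile, a pseudocount of 0.0921, leaving out the dimmest 30% or 50% of probes, complete probes alone, other variance priors, array weights, a paired test without moderation and leaving out each mouse. Alternatives added after seeing the data were cyclic loess, probes with a symbol alone, the 20th percentile floor without probes at the floor on every array, and fits within mice 183 and 197 and within mice 438 and 440. No date or scan batch was given in the sources used here.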

Results

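Gene expression was measured in 4 stimulated and 4 contralateral EDL muscles, 1 pair from each of mice 183, 197, 438 and 440. The comparison asks how 4 h of nerve-driven contraction alters transcript levels in a fast muscle, with each animal as its own control. Array medians ranged from 0.90 to 0.94 intensity units and the number of probes with a value from 10367 to 10474 per array.

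In stimulated muscle 11 of 27 measured immediate early genes, 3 of 13 cytokine genes and 4 of 16 regulators of fibre type rose, and single genes of fuel use and protein breakdown fell. None of these lists passed with an estimated correlation (adjusted p = 0.126, 0.267 and 0.126). The largest rise was in Ccl7, a chemokine that attracts monocytes, at 12.6-fold (log2 change 3.66 ± 0.33, SE, n = 4 mice). The largest fall was in the methyltransferase Inmt, at 4.17-fold (log2 change -2.06 ± 0.29, n = 4). Fbxo32, a ubiquitin ligase of muscle atrophy, was 3.20-fold lower and Pdk4, a kinase that restrains pyruvate oxidation, was 3.01-fold lower.

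In all, 139 of 10406 probes changed at adjusted p 0.05 with limma, 115 of them higher and 24 lower, and 135 changed at least 2-fold. Of these, 105 have a gene symbol, 88 higher and 17 lower. All 139 moved the same way in every mouse with values. Among probes with a gene symbol, the other largest rises were in Gem, a small GTPase (3.19 ± 0.25 on the log2 scale), Rcan1 (3.00 ± 0.34), Timp1, an inhibitor of matrix metalloproteinases (2.79 ± 0.51), the chemokine Ccl2 (2.72 ± 0.50), the transcription factor Egr1 (2.63 ± 0.35), the secreted protease Adamts1 (2.59 ± 0.24), the heme-degrading enzyme Hmox1 (2.48 ± 0.46), the secreted pattern recognition protein Ptx3 (2.45 ± 0.26), Fos (2.43 ± 0.25), the cytokine signalling inhibitor Socs3 (2.41 ± 0.33) and the transcriptional coactivator Ppargc1a (2.37 ± 0.23). Some of these were dim in contralateral muscle, as Egr1, Fos, Gem and Timp1 at mean log2 intensities of -1.52, -0.90, -0.71 and -0.45. The other largest falls among probes with a gene symbol were in Zfp112 (-1.86 ± 0.22), Fibin (-1.74 ± 0.22), the alcohol dehydrogenase Adh1 (-1.57 ± 0.20), the glutathione transferase Gsta3 (-1.56 ± 0.30), the neuropeptide Y receptor Npy1r (-1.51 ± 0.26), the mitochondrial carrier Ucp3 (-1.49 ± 0.26), the thioredoxin-binding protein Txnip (-1.37 ± 0.19), Prom1 (-1.31 ± 0.22) and the lipid droplet protein Plin4 (-1.30 ± 0.18). Gsta3 was dim, at a contralateral mean of -1.02 and with 1 stimulated muscle at the floor. Mouse 440 carried part of several rises: without it the log2 changes of Timp1, Ccl2 and Hmox1 were 2.05, 1.90 and 1.74, and each still passed; Timp1 was at 3.38 without mouse 438. Within a group of 4 muscles, 1 muscle stood apart for Gem, Ppargc1a and Adh1 in stimulated EDL and for Plin4 in contralateral EDL.

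**Figure D1:**
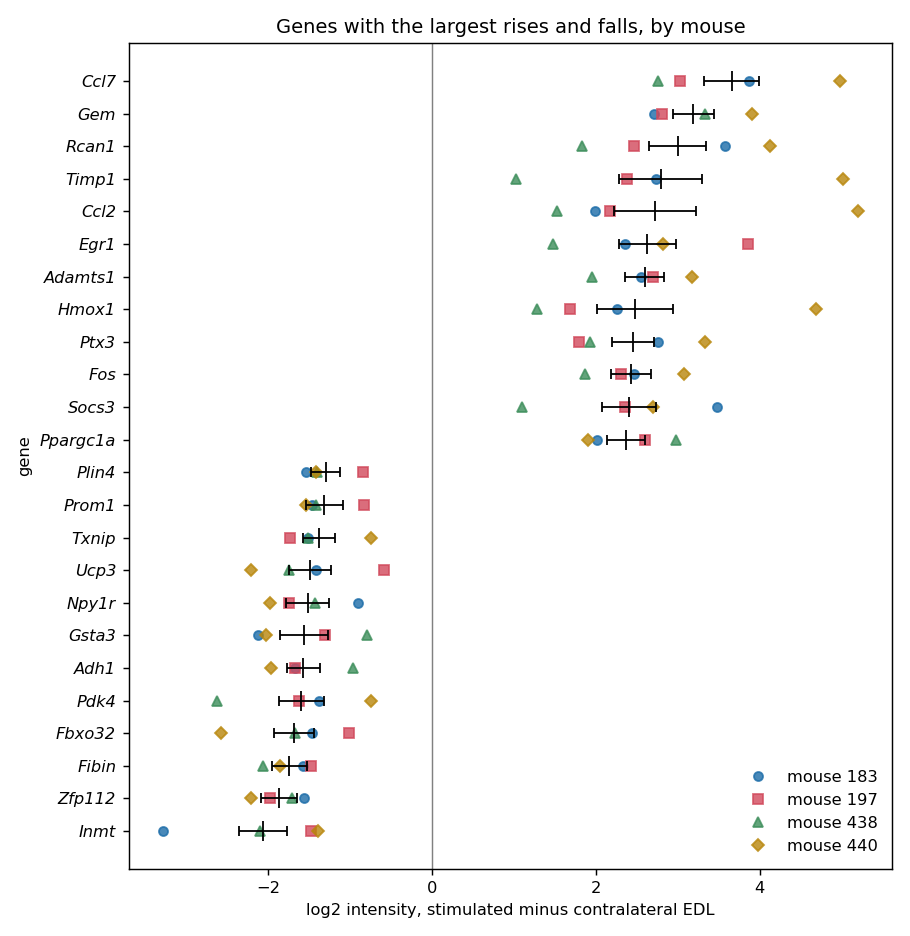
Change in each mouse of the 12 genes with the largest rises and the 12 with the largest falls, as log2 intensity of the stimulated minus the contralateral muscle on the horizontal axis, with 1 row per gene. Coloured symbols are the 4 mice, the black tick is the fitted mean and the bar its moderated SE. All values of the upper 12 genes lie above 0 and all of the lower 12 below 0, from Ccl7 at 3.66 to Inmt at -2.06.

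These counts rest on the pairing and on single animals: 1 probe passed without mouse as a block (477 at unadjusted p under 0.05), 7 without mouse 183 and 67 without mouse 197, and 13 in place of 24 were lower without mouse 438. With limma replaced by a paired test without moderation, or with the floor at the 20th percentile, 0 probes passed, against 1208 and 1296 at unadjusted p under 0.05.

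The arrays also differed between mice 183 and 197 on the one side and mice 438 and 440 on the other, where 56 probes lacked values on all 4 arrays of the first pair alone and 25 on all 4 arrays of the second pair alone. Within mice 183 and 197, limma called 0 probes (865 at unadjusted p under 0.05), and within mice 438 and 440 it called 79 (1119 at unadjusted p). The interaction of stimulation with this split reached adjusted p 0.05 for 0 probes and unadjusted p 0.05 for 319, of which 3 were among the 139 called. All 139 had the same direction in the mean of each pair of mice, which follows from their moving the same way in every mouse with values.

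Immediate early genes, which cells switch on soon after a stimulus, had the highest median change of the tested lists. Of 27 measured members 11 rose, 0 fell and 16 did not pass, and 18 rose when adjusted over the list alone. Fos (5.39-fold), Egr1 (6.19-fold), the zinc finger factor Klf4 (3.42-fold) and the orphan nuclear receptor Nr4a1 (2.73-fold) had the smallest p. Atf3 and Mafk, both leucine zipper transcription factors, rose 5.10-fold and 4.97-fold, with Atf3 at a log2 change of 1.73 without mouse 440 in place of 2.35; Nr4a1 had 1 contralateral muscle and Mafk 1 stimulated muscle apart from the other 3. The median change was 1.35 against -0.11 for lists matched on brightness, with an adjusted camera p of 3.7e-17 and adjusted p = 0.126 with an estimated correlation. The study itself named 5 of the members from these samples, so their part of the count is not independent evidence. One of them, Jun, did not pass (log2 change 1.29 ± 1.04), with changes of 3.86 and 4.90 in mice 183 and 438 and of -2.50 and -1.08 in mice 197 and 440.

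**Figure D2:**
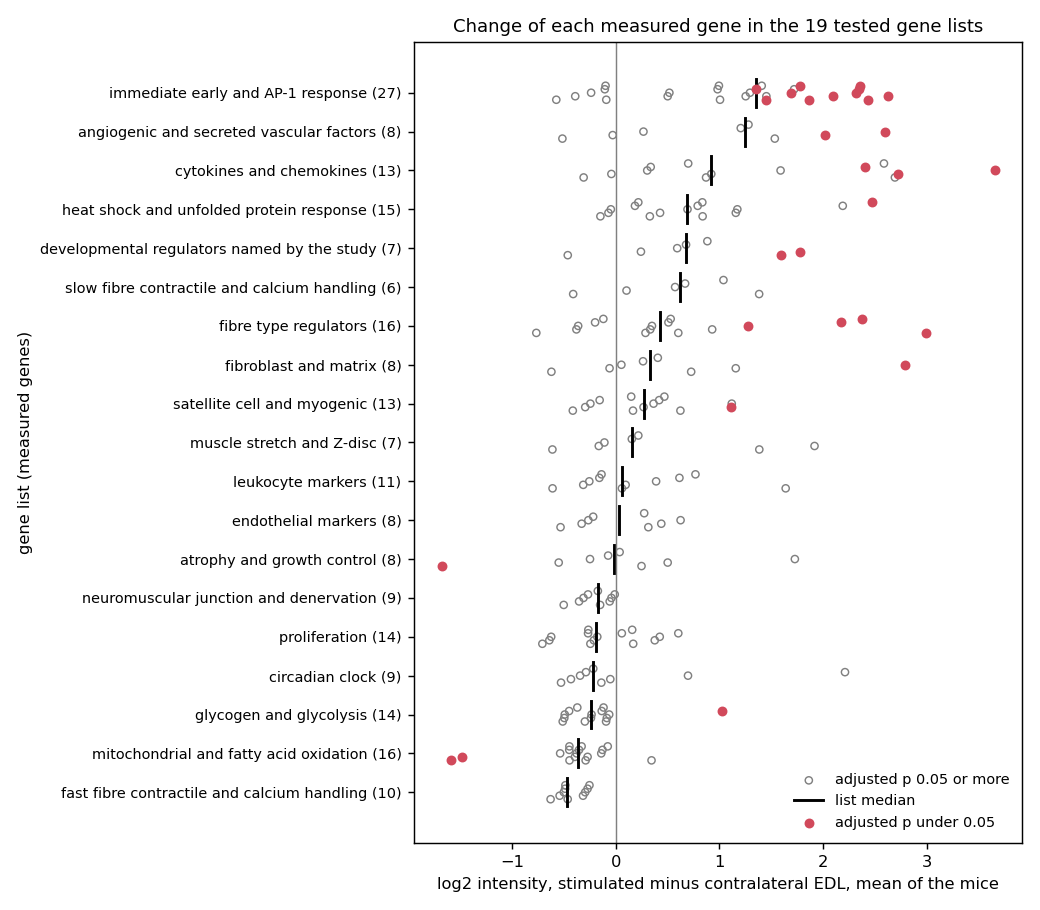
Log2 change, stimulated minus contralateral EDL, of each measured gene in the 19 tested lists, 1 row per list with the number of measured genes in brackets. Filled circles passed adjusted p 0.05 over all probes, open circles did not, and black ticks are list medians, from -0.47 for fast fibre genes to 1.35 for immediate early genes.

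Transcripts of the fast contractile apparatus were lower as a list in camera's test, a call that ended with an estimated correlation (adjusted p = 0.267 with an estimated correlation) and after quantile normalization (adjusted p 0.382). None of the 10 measured members passed over all probes, but all 10 had negative changes and 6 fell when adjusted over the list alone. Among these were the fast troponin Tnni2 (log2 change -0.50 ± 0.15), muscle creatine kinase Ckm (-0.54 ± 0.16), the calcium buffer parvalbumin Pvalb (-0.49 ± 0.15) and the fast myosin light chain Mylpf (-0.49 ± 0.15), each negative in 4 of 4 mice. The list median was -0.47, against -0.23 for lists drawn from the genes nearest in brightness, and the adjusted camera p was 1.0e-04. Most members are among the brightest probes, as Tnni2 at a contralateral mean of 10.8, so the genes drawn for them were mostly dimmer. Quantile normalization left a list mean of -0.09 in place of -0.42, and after it Tnnt3 stood at 0.04 in place of -0.30. Over the alternatives that kept all mice, the highest values were 0 for Tnni2, -0.12 for Pvalb, -0.12 for Mylpf and -0.22 for Ckm. The study named 3 of the 10 measured genes, Ckm, Tnnt3 and Tpm1 (-0.32 ± 0.16), and their direction is not independent evidence.

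Slow fibre transcripts had a positive mean change in 3 mice (0.49, 0.75 and 1.14 in mice 183, 197 and 438) and a negative one in mouse 440 (-0.15). Of 6 measured members 0 passed over all probes and 3 rose when adjusted over the list alone: the slow troponins Tnnc1 (log2 change 1.38 ± 0.32, higher in 3 of 4 mice) and Tnnt1 (1.04 ± 0.24, 4 of 4) and the slow tropomyosin Tpm3 (0.57 ± 0.18, 4 of 4). The slow troponin Tnni1 changed by 0.67 ± 0.32 and did not pass. Together they had a median of 0.62, with adjusted camera p 0.0025 and adjusted p = 0.28 with an estimated correlation; without mouse 438 the mean was 0.37 in place of 0.56 (adjusted p 0.0413). Tnnc1 and Tpm3 were named by the study from these samples and are not independent evidence of the direction.

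Among 16 measured regulators of fibre type 4 rose, 0 fell and 12 did not pass, and 5 rose when adjusted over the list alone. Ppargc1a, a coactivator of mitochondrial and slow fibre genes, rose 5.18-fold, Bhlhe40, a transcriptional repressor also tied to the clock, rose 4.51-fold, Rcan1, an inhibitor of the phosphatase calcineurin, rose 7.98-fold and Eya1, a transcriptional coactivator, rose 2.42-fold. Pparg (0.93 ± 0.22), Nfatc1 (0.60 ± 0.23), Tead1 (0.53 ± 0.24) and Nfatc4 (0.35 ± 0.21) had positive log2 changes that did not pass over all probes. For this list the median was 0.43, with adjusted camera p 5.6e-06 and adjusted p = 0.126 with an estimated correlation. The study picked 7 of these 16 genes from these samples, Rcan1 not among them, so the count is not independent evidence.

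Of 7 developmental regulators that the study named, 2 rose, 0 fell and 5 did not pass, and 3 rose when adjusted over the list alone. Klf4 rose 3.42-fold and Sox17, a factor of endoderm and vessel development, rose 3.01-fold. Tcf15 (0.88 ± 0.24) and Pknox1 (0.59 ± 0.25) were positive in 4 of 4 mice and did not pass over all probes; Elavl4 (0.68 ± 0.32) and Elavl1 (0.24 ± 0.24) were positive and Elavl2 (-0.46 ± 0.30) negative. Their median was 0.68 (adjusted camera p 3.3e-05, adjusted p = 0.127 with an estimated correlation). Since the whole list was chosen by the study on these samples, it is not independent evidence.

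Satellite cell and myogenic genes mark the resident stem cells of muscle and their descendants. Of 13 measured members 1 rose, 0 fell and 12 did not pass, over all probes and adjusted over the list alone. The member that rose was Sdc4, a cell surface proteoglycan (2.16-fold), which other muscle cells also make. The myogenic factors Myod1 (1.12 ± 0.46), also named by the study, and Myf5 (0.62 ± 0.34) and the receptor Met (0.42 ± 0.22) did not pass. Without 1 mouse they ranged from 0.49 to 1.60, from 0.39 to 1.11 and from 0.22 to 0.57, with Myod1 lowest without mouse 440 and Myf5 and Met lowest without mouse 438. As a list they had a median of 0.27 with adjusted camera p 0.0089 (adjusted p = 0.267 with an estimated correlation), and the call ended without mouse 440, where the mean was 0.15 in place of 0.28 (adjusted p 0.138), and without the dimmest 50% of probes, where the mean was 0.32 (adjusted p 0.0583). Among 14 proliferation genes 0 passed over all probes or over the list alone. Pcna, a replication clamp, had a log2 change of 0.60 ± 0.20, with the stimulated muscle of mouse 440 apart from the other 3, while Ccne1 (-0.71 ± 0.25), Ccna2 (-0.64 ± 0.27) and Plk1 (-0.62 ± 0.35) were negative. Ccnb2 (0.38 ± 0.27) and Ccnc (-0.18 ± 0.21), also named by the study with Ccne1 and Ccna2, did not pass. Proliferation genes had a median of -0.19 and its mean -0.10, both negative, with camera's direction up and adjusted p 0.973.

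Cytokine and chemokine transcripts were higher as a list in camera's test, but did not pass with an estimated correlation (adjusted p = 0.267 with an estimated correlation). Of 13 measured cytokine genes 3 rose (Ccl7 12.6-fold, Ccl2 6.59-fold, with a log2 change of 5.19 in mouse 440 and 1.53 to 2.17 in the others, and Socs3 5.30-fold), 0 fell and 10 did not pass, and 8 rose when adjusted over the list alone. Il6, a cytokine that contracting muscle releases, had a log2 change of 2.69 ± 0.54, higher in 4 of 4 mice, and adjusted p 0.0507. Cytokine genes had a median of 0.92, with adjusted camera p 6.7e-08. Mean changes of the list were 1.22, 1.34, 0.52 and 2.63 in mice 183, 197, 438 and 440. Of 11 leukocyte markers 0 passed over all probes and 1, the endotoxin co-receptor Cd14 (1.64 ± 0.40, and 1.00 without mouse 440), rose when adjusted over the list alone. Fcgr3 (0.61 ± 0.21) was positive in 4 of 4 mice, S100a8 (0.77 ± 0.35) was at 0.22 without mouse 440, and Ccr2 (-0.61 ± 0.40, n = 3) was negative; for Ccr2 the stimulated muscle of mouse 183 stood apart from the others. The leukocyte list median was 0.06, with adjusted camera p 0.0818; the mean of its genes in the set test was 0.27, against 0.42 without mouse 183, where it passed (adjusted p 0.012), and 0.048 without mouse 440 (adjusted p 0.513). It also passed without the dimmest 50% of probes, with a mean of 0.63 (adjusted p 0.035), and with the floor at the 20th percentile without probes at the floor on every array, with a mean of 0.31 (adjusted p 0.0491).

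Heat shock and unfolded protein response transcripts had a positive mean change in 3 mice and a negative one in mouse 197. Of 15 measured members 1 rose, Hmox1 (5.56-fold), 0 fell and 14 did not pass; 2 rose when adjusted over the list alone, Hmox1 and the cochaperone Dnajb1 (log2 change 2.19 ± 0.50). Hsph1 (1.17 ± 0.37) and Hsp90aa1 (1.16 ± 0.41), chaperones of the cytosol, did not pass. Across the 15 genes the median was 0.69, with adjusted camera p 3.3e-05 and adjusted p = 0.335 with an estimated correlation. Mean changes of the list were 1.07, 0.62 and 1.60 in mice 183, 438 and 440 and -0.35 in mouse 197, where the SE over the genes was 0.20. In the stimulated muscle of mouse 197, 12 of the 15 genes were lower, and 8 of these 12 were higher in the other 3 mice. The contralateral muscle of mouse 197 held Dnajb1 at a log2 intensity of 4.91, where the other 3 contralateral muscles had 1.92, 3.30 and 2.88. Without mouse 197 the list mean was 1.10 in place of 0.74 (adjusted p 2.3e-11), and without mouse 440 it was 0.45 (adjusted p 0.0107).

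**Figure D3:**
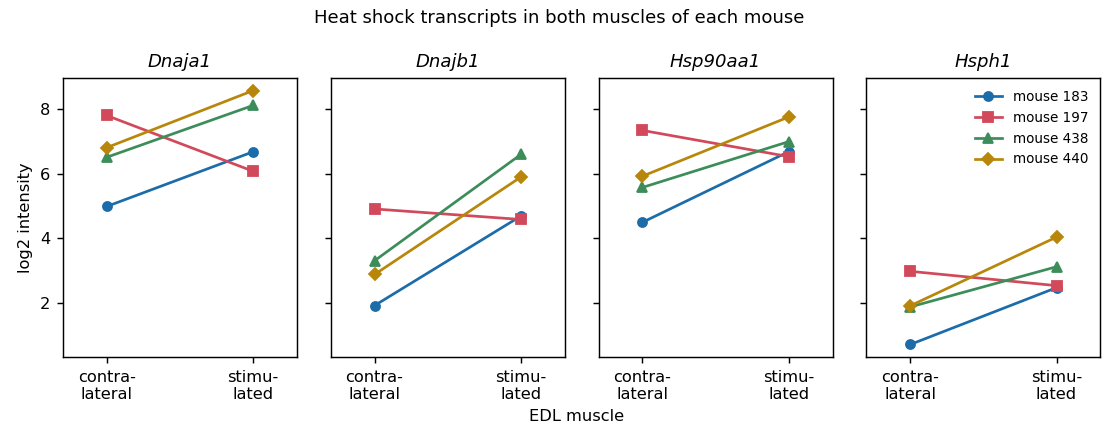
Log2 intensity of Dnaja1, Dnajb1, Hsp90aa1 and Hsph1 in the contralateral and the stimulated EDL, with a line joining both muscles of each mouse. The lines of mice 183, 438 and 440 go up and those of mouse 197 go down, as for Hsp90aa1 from 7.34 to 6.53. Of the 15 list members 8 had this pattern, and Dnaja1, outside the naming rule, was chosen after its values were seen.

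Among genes of glucose and fatty acid use Hk2 rose and Pdk4 and Ucp3 fell. In the list of glycogen and glycolysis genes, Hk2, the hexokinase that traps glucose in muscle, rose 2.04-fold, 0 of 14 fell and 13 did not pass; adjusted over the list alone 1 rose and 2 fell, phosphorylase kinase Phkg1 (-0.51 ± 0.16) and phosphofructokinase Pfkm (-0.50 ± 0.15). Gapdh had a log2 change of -0.37 ± 0.17 (n = 3). Glycolysis genes had a median of -0.24 with adjusted camera p 0.278. Without mouse 183 the list passed, with a mean of -0.26 (adjusted camera p 0.0411), and without mouse 440 the mean was -0.022 (adjusted camera p 0.932). The mean of the genes in the set test was -0.17 in the main fit, -0.026 after quantile normalization and -0.019 after cyclic loess. Of 16 mitochondrial and fatty acid oxidation genes 2 fell, Pdk4 (3.01-fold) and Ucp3 (2.80-fold), 0 rose and 14 did not pass, with the same counts adjusted over the list alone. Both are genes that fasting and fatty acids induce, while components of the citric acid cycle and respiratory chain such as Mdh2 (-0.54 ± 0.21) and Cox6a2 (-0.45 ± 0.18) did not pass, and stood at -0.29 and -0.25 without mouse 440. Mitochondrial genes had a median of -0.37, with adjusted camera p 0.0016 and adjusted p = 0.286 with an estimated correlation. Among 8 genes of atrophy and growth control 1 fell, Fbxo32, 0 rose and 7 did not pass. Adjusted over the list alone 1 rose, the activin and myostatin antagonist Fst (1.73 ± 0.42, and 1.14 without mouse 440), and 2 fell, Fbxo32 and Foxo1 (-0.55 ± 0.19), a transcription factor that induces Fbxo32; Gadd45a was higher in 2 mice and lower in 2. That list's median was -0.02, below 0, with camera's direction up and adjusted p 0.974.

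Angiogenic and secreted vascular factors passed camera's test as a list, but not with an estimated correlation (adjusted p = 0.267 with an estimated correlation) or in fry's directional test (adjusted p 0.0773), and endothelial markers passed none of these. Of 8 angiogenic factors 2 rose, 0 fell and 6 did not pass, and 5 rose when adjusted over the list alone. Adamts1 rose 6.04-fold and the hypoxia-responsive transcription factor Hif1a 4.04-fold. The endothelial growth factor Vegfa (log2 change 1.21 ± 0.25) and the urokinase receptor Plaur (1.53 ± 0.40, and 1.01 without mouse 440) were higher in 4 of 4 mice and did not pass over all probes. Angiogenic factors had a median of 1.24, with adjusted camera p 7.4e-06. Of 8 endothelial markers 0 passed over all probes or over the list alone, with a median of 0.03 and adjusted camera p 0.343. Kdr (0.63 ± 0.19), Emcn (0.44 ± 0.26) and Eng (0.31 ± 0.21) were positive, and Cdh5 was at -0.53 ± 0.33 with 2 stimulated muscles at the floor. Of 8 fibroblast and matrix genes 1 rose, Timp1 (6.91-fold), 0 fell and 7 did not pass, and 2 rose when adjusted over the list alone, with the matrix glycoprotein Tnc (1.16 ± 0.34, and 0.72 without mouse 440). Lox (0.73 ± 0.38, and 0.22 without mouse 440) was positive and the collagen-binding proteoglycan Lum (-0.62 ± 0.22) negative. The list median was 0.33 with adjusted camera p 0.0148 (adjusted p = 0.267 with an estimated correlation); the call ended without mouse 197 (adjusted p 0.08) and without the dimmest 30% and 50% of probes (adjusted p 0.0576 and 0.108), with means of 0.55, 0.59 and 0.62 against 0.59 in the main fit.

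Markers of nerve, fat and blood were measured by too few genes for a list test. Pmp22 of Schwann cells was at 0.52 ± 0.23 and Mag at 0.09 ± 0.25 on the log2 scale. Of 3 adipocyte markers the lipid-binding Fabp4 (0.66 ± 0.17), also made by capillary endothelium, rose when adjusted over the list alone and not over all probes, with Lpl at -0.34 ± 0.16 and Retn at -0.57 ± 0.33. Haemoglobin alpha Hba-a1 (-0.18 ± 0.26) and the red cell anion exchanger Slc4a1 (0.22 ± 0.50) did not pass; Hba-a1 had 1 contralateral and Slc4a1 1 stimulated muscle far from the others, and Hba-a1 stood at 0.21 after quantile normalization. Of 9 genes of the neuromuscular junction and denervation 0 passed over all probes or over the list alone. All 9 were negative, with Chrna1 at -0.35 ± 0.19, Ache at -0.50 ± 0.28, Chrne at -0.31 ± 0.21 and Musk at -0.27 ± 0.30. The median was -0.17, within the central range of lists matched on brightness (-0.38 to 0.22, median -0.12), and the adjusted camera p 0.421.

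Stretch-responsive genes and clock genes did not pass as lists. Of 7 stretch and Z-disc genes 0 passed over all probes, while adjusted over the list alone the actin-binding Xirp1 (1.38 ± 0.46) rose and Fhl1 (-0.61 ± 0.16) fell. Xirp1 changed by 2.42 and 2.99 in mice 183 and 440 and by 0.045 and 0.083 in mice 197 and 438, and was at 0.85 without mouse 440. The ankyrin repeat protein Ankrd1 was at 1.92 ± 0.86, with the stimulated muscle of mouse 438 far below the other 3, and Actc1 at -0.16 ± 0.19. That list had a median of 0.15 and adjusted camera p 0.402, and passed without mouse 438 with a mean of 0.92 (adjusted p 0.0019), against 0.40 with all mice and 0.033 without mouse 440 (adjusted p 0.932). Of 9 clock genes 0 passed over all probes or over the list alone. Clock was at 2.21 ± 0.65, with changes of 2.33, 0.11, 5.21 and 1.20 in mice 183, 197, 438 and 440 and a value of 1.21 without mouse 438. Nr1d2 was at 0.70 ± 0.29, and 0.44 without mouse 197, and Per2 (-0.43 ± 0.22) and Dbp (-0.29 ± 0.16) were lower in 4 of 4. Clock list members had a median of -0.22 and a mean of 0.10, opposite in sign, with camera's direction down and adjusted p 0.974; fry's mixed test gave adjusted p 0.0027.

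Across the lists, camera called 11 of 19, 9 up and 2 down, and 0 held with an estimated correlation. Fry's directional test called 3 (immediate early, fibre type regulators and developmental regulators). From these samples the study had named the whole developmental list, 7 of 16 fibre type regulators and 5 of 27 immediate early genes. Fry's mixed test also called 11, the same lists as camera but for these: slow fibre and heat shock genes were out (adjusted p 0.13 and 0.19), and glycolysis and clock genes were in (adjusted p 0.0117 and 0.0027). Of 32 genes that the study named, 28 were measured here, of which 8 rose, 0 fell and 20 did not pass, 13 of these with a positive and 7 with a negative change. Of the 34 named genes that passed, all 34 lost the call without mouse as a block, with the floor at the 20th percentile and in the paired test without moderation, 29 lost it without mouse 183 and 14 without mouse 197. Of the 73 that did not pass, 37 moved by over 1.5 times when 1 mouse was left out, 26 of them without mouse 440. For the 34, 0 of 711 values under the alternatives had the opposite direction. Leaving out a mouse could not give one, since all 34 moved the same way in every mouse with values. Alternatives that alter the variance estimate alone could not either.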

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

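For 107 named genes, each group of 4 muscles was searched for 1 muscle whose gap to its nearest neighbour, as a share of the group's range, exceeded Dixon's 95% critical value. Chance flags about 1 in 20 such groups and 12 of 212 stood out. The search compared levels and not paired changes, so a flag can mark a mouse in which both muscles were low or high. Gem in mouse 438, for example, changed by 3.34, within the range of the other mice (2.71 to 3.90). Ankrd1 in mouse 438 changed by -2.22, outside theirs (1.74 to 4.31). No explanation was tested for the flagged values.

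Among genes that rose, Gem in the stimulated muscle of mouse 438 was at a log2 intensity of 1.11, where the other 3 stimulated muscles had 2.76 to 3.07. Ppargc1a in the stimulated muscle of mouse 440 was at 1.68, below 3.43 to 3.75 in the others. Mafk in the stimulated muscle of mouse 438 was at 2.63, below 3.37 to 3.46. Nr4a1 in the contralateral muscle of mouse 440 was at 4.17, above 3.01 to 3.20. Among genes that fell, Adh1 in the stimulated muscle of mouse 438 was at 4.39, above 2.89 to 3.09, and Plin4 in the contralateral muscle of mouse 197 was at 4.67, below 5.65 to 5.81.

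Among genes that did not pass, Pcna in the stimulated muscle of mouse 440 was at 6.14, above 5.04 to 5.22, and Cdh5 in the same muscle was at -1.32, above -3.42 to -3.10. Ccr2 in the stimulated muscle of mouse 183 was at -1.51, above -2.40 to -2.32. Hba-a1, which blood left in the tissue would carry, was at 11.39 in the contralateral muscle of mouse 440, above 9.62 to 9.92. Slc4a1 in the stimulated muscle of mouse 438 was at 0.30, above -3.42 to -3.25. Ankrd1 in the stimulated muscle of mouse 438 was at 2.40, below 6.22 to 6.98.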

How the results depend on the processing

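All 139 probes kept their direction under every alternative in which they were tested, but the number passing did not keep. The direction was fixed in advance where a mouse was left out, since all 139 moved the same way in every mouse with values. It was also fixed where the variance estimate alone changed. Without mouse as a block 1 probe passed, 1 higher and 0 lower, 1 of them at least 2-fold. The mouse as a random effect gave 202 probes with 42 lower, and array weights gave 217 with 175 higher and 42 lower. Without the intensity trend 50 passed, 45 higher and 5 lower, all 50 at least 2-fold. The paired test without moderation and the floor at the 20th percentile gave 0 probes, 0 higher, 0 lower and 0 at least 2-fold. With probes at that floor on every array left out, an alternative chosen after seeing the data, 19 passed, 17 higher and 2 lower, all 19 at least 2-fold. The cause of these shifts was not tested. Counts under quantile normalization, median scaling, no floor, a pseudocount, both filters on dim probes, complete probes, the robust prior, and, chosen after seeing the data, probes with a symbol and cyclic loess lay between 102 and 156. Leaving out each mouse gave 7 to 176 probes, 7 to 149 higher, 0 to 27 lower and 7 to 162 at least 2-fold, the lowest each time without mouse 183.

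Camera's 11 calls became 0 with an estimated correlation and 3 with fry's directional test, and lay between 10 and 12 under the other settings and between 10 and 13 when a mouse was left out. Of the named genes that had not passed, Hba-a1 turned to 0.21 under quantile normalization and 0.070 under cyclic loess (-0.52 to 0.13 over mice left out), Tnnt3 to 0.036 under quantile normalization, and Cdh5 to 0.015 with either form of the 20th percentile floor. Leaving out mice gave Mag -0.057 to 0.24 and Slc4a1 -0.49 to 0.70. The floor understates changes of dim genes, such as Elavl4 with 2 contralateral muscles at it.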

Other observations

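Of the 105 genes with a symbol that changed, 77 lie outside the fixed lists, 63 higher and 14 lower; those named here were chosen after their values were seen. The matrix metalloproteinase Mmp3 rose by 2.35 ± 0.36 on the log2 scale, and the serum amyloid genes Saa1 (2.25 ± 0.45) and Saa3 (2.21 ± 0.31), known from the acute phase response, rose with the chemokines Ccl11 (2.33 ± 0.40), Cxcl14 (1.72 ± 0.30) and Ccl24 (1.53 ± 0.29). The cytokine signalling inhibitors Socs1 (1.89 ± 0.31, n = 3) and Cish (1.53 ± 0.27) rose as Socs3 did. Dio2, the deiodinase that activates thyroid hormone, rose by 1.87 ± 0.27, the placental growth factor Pgf by 1.88 ± 0.22, and the flow-responsive factor Klf2 by 1.61 ± 0.23 (n = 3). Pfkp, a phosphofructokinase isoform, rose by 1.21 ± 0.17, whereas the muscle isoform Pfkm was at -0.50 ± 0.15 and did not pass over all probes. Pfkm is a bright probe and stood as high as -0.18 over the alternatives that kept all mice. The glucocorticoid-induced Tsc22d3 had the smallest change among the called probes (-0.84 ± 0.15).

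Apart from the regrouping of the arrays and the quantile normalization, which were fixed beforehand, the tests of explanations in this part were chosen after the results were seen. Of the 35 ways to part the 8 arrays into 4 and 4, 8 part all 4 pairs, which is too few for a share under 0.05. Among these 8, only 1, the real one, gave as many as 139 probes, and likewise only 1 as many as 115 higher, 1 as many as 24 lower and 1 as many as 135 at least 2-fold; the highest of the others was 0 each time. For the list tests 2 of the 8 gave 11 calls, the real one and the one that reverses mouse 183 alone. The 4 splits that reverse 1 mouse, and so keep stimulation against control in the other 3, gave 1 to 11 list calls, and the 3 that reverse 2 mice gave 2 to 4. The 24 splits that part 2 pairs gave at most 7 probes but 0 to 12 list calls, and 4 of them gave 12, more than the real split. Of these 24, the 12 that part both pairs the same way, and so keep stimulation against control in 2 mice, gave 7 to 12, and the 12 that part them in opposite ways gave 0 to 6. Without a block for mouse, parting mice 183 and 197 from mice 438 and 440 gave 2301 probes against 1 for the real split, which points to a structure of the samples that the block takes up.

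The heat shock pattern of mouse 197 has 2 parts, a negative mean change in that mouse and a high contralateral level. Swapped arrays are argued against, since 86.6% of the probes called without mouse 197 moved the same way in it. Whether scaling bears on the negative change stays open, as the list's mean change in this mouse was within 2 SE of 0 both as deposited (-0.35 ± 0.20, SE over the genes) and after cyclic loess (-0.11 ± 0.20). Scaling is argued against for the high contralateral level: after cyclic loess the list median there exceeded the mean of the other 3 mice by 0.85, at percentile 100 of lists matched on brightness, whose central range was -0.33 to 0.32. The design offers no biological group for this muscle, so no biological explanation was tested.

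The rise of Ccl2, Ccl7 and Socs3, with a median of 2.72, may come from cells already in the muscle, from their share, or from cells that entered it. A larger share of the leukocytes already present would need their markers to move alike, but the 4 markers above the median level (Lyz2, Cd14, S100a8 and Fcgr3) had a median of 0.69 ± 0.78 (SD). A larger share of connective tissue cells would need the fibroblast and matrix list to do the same, and its median was 0.33 ± 1.03 (SD). Both medians lie below 2.72, but that value comes from the 3 cytokine genes that passed, and all 13 measured had a median of 0.92. The comparison therefore excludes neither share. Both shares, entry of a few cells rich in these transcripts, and induction by contraction within resident cells, stay open. Stimulation is the one difference the design names between the muscles, and handling of the stimulated leg apart from contraction was not tested.

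The lower fast fibre transcripts lie among the brightest probes, where all 287 genes above a log2 intensity of 6 had a median change of -0.23. A smaller share of muscle fibre RNA alone would lower both fibre lists, but the slow fibre list exceeded the fast fibre list by 0.98 ± 0.18 (SE over 4 mice). A smaller share joined by a rise of slow fibre genes would give such a difference too, so that explanation stays open. In mouse 440 both list means were negative, at -0.15 for slow and -0.70 for fast fibre genes. A shift of all bright probes cannot be told apart from a fall of these genes. The list median lay at percentile 0.02 of lists matched on brightness, but most members are among the brightest probes and the genes drawn for them were mostly dimmer. That comparison therefore cannot decide the question. The camera call held after cyclic loess (mean -0.19, adjusted p 0.0104), but quantile normalization took the mean from -0.42 to -0.09 and ended the call. By construction that step gives the brightest ranks of every array the same values.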
